A study of Capra hircus with 7 samples.

How the data were processed

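RNA sequencing gave 7 libraries of goat (Capra hircus) primary mammary epithelial cells at passage 3, from cells whose source is given as milk. Of these, 3 were of cells infected with Escherichia coli, 3 with Staphylococcus aureus, and 1 was an uninfected control. Total RNA was taken with Trizol and made into libraries with an Illumina TruSeq kit, per the labels' protocols. The dose and duration of infection, the bacterial strains and the number of goats are not given in the sources used here. Nothing says whether libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

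Per the submitters' processing notes, reads passed through FastQC, Trim Galore, Bowtie, TopHat and Cuffdiff, with no versions or genome build given; the design text also names Cufflinks and coding-potential filters for long noncoding RNAs. The table used holds 666 rows, each with an Ensembl goat gene identifier, and 1 column per library, so that the infected libraries were not averaged. The design text speaks of triplicates while the labels give 1 control library, and whether that library is a pool is not stated. No column lacks a sample, no value is missing and no identifier is repeated. The values are treated as a score, as deposited by the authors: their unit, transformation and normalization are not stated. The name of the deposited table gives RPKM, but the values run from 4.17 to 17.4 and the spread between replicates grows little with the level (median residual SD 0.333, 0.352 and 0.357 in the 222 genes of lowest, middle and highest mean level). Values on a log-like scale behave in that way. Read as powers of 2 they would sum to between 1814416 and 2230807 per library over these rows alone, above the 1000000 that CPM allows. That sum speaks only against CPM on base 2, as RPKM has no such limit, and leaves the base open. Differences are given in deposited units, and no fold change is reported. If the base were 2, a difference of 1 unit would be a 2-fold change. Read depth is unknown from these values.

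How the 666 rows were chosen is not stated, nor whether they are coding genes or long noncoding RNAs. Every row varied by at least 0.31 units over the 7 libraries. A selection on variability would raise the apparent spread between replicates, and a selection on a comparison would raise differences. The files do not pair the identifiers with gene names, and the reference table used here (28911 goat genes, 0 with an Ensembl identifier) matched 0 of them. The 25 gene lists fixed before the data were examined (chemokines, cytokines, NF-kB pathway, interferon-stimulated genes, milk proteins, keratins, other cell types and the like) were therefore not tested, and neither symbols nor positions are given. A further table was not used: all 681912 of its rows carry chicken identifiers, and 0 of its 8 sample codes match a label of this series. It holds 2 columns of per-sample values, which entered no step.

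The comparisons were E. coli against control, S. aureus against control, and E. coli against S. aureus. They were fitted together with limma (version 3.58.1, R 4.3.3) on the deposited values, with 1 mean per group, an intensity trend and no covariates. Calls were made at a Benjamini-Hochberg adjusted p of 0.05 over the 666 genes, two-sided. The lone control is assumed to vary like the infected libraries, which would not hold for a pool. E. coli and S. aureus libraries are likewise assumed to share 1 spread, although the S. aureus libraries differed more from each other than the E. coli libraries did. The design fixed before the data were examined assumed linear FPKM with a pseudocount and an expression filter; neither applies to values already on a log-like scale, so no constant was added and no gene was removed. limma set the prior degrees of freedom to infinity, so that genes of like level share 1 spread. An exact permutation test of 3 libraries against 3 cannot go below 0.1, and of 3 against 1 not below 0.5 (two-sided), so no such test was made per gene. The rule for naming genes, fixed beforehand, required symbols; the identifiers named are instead among the 2 largest rises and the 2 largest falls of each comparison, and this rule was chosen after their values were seen.

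On simulated data with an SD of 0.354 between libraries and 200 of 666 genes changed (20 simulations per comparison), a change of 1 unit was recovered for 81.8% of genes between the infections, and one of 0.5 for 20.8%. Against the control, E. coli changes of 1 and 1.5 units were recovered for 38.2% and 82.5% of genes, and S. aureus changes for 42.6% and 84.9%. The changed genes took sizes of 0.5, 1, 1.5 and 2 units in equal shares. The noise was equal and independent in all libraries, with no pairing by number. It also had the same SD for every gene, as the fitted model assumes. In the data the S. aureus libraries differed more from each other than the E. coli libraries, so the shares may not hold there. Where few genes change, the adjusted threshold is stricter, so these shares are too high for that case.

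The labels number the E. coli and S. aureus libraries 1 to 3. Deviations from the group mean across genes correlated between same-numbered libraries at r = 0.49, 0.59 and 0.31 for numbers 1, 2 and 3. All 3 were above 0.1 and each library correlated best with its own number, so the numbers were treated as pairs where stated. This pairing comes from the data, not from a label, and is not established. The 3 correlations are not independent, since the deviations within a group cancel out for each gene. The 6 possible pairings are too few to tell it from chance. The fit without the block stays the reported one, as fixed beforehand. Alternatives were other scalings of the libraries, other variance models, each infected library left out, the 6 infected libraries alone and the replicate number as a block. Figures were drawn with matplotlib (version 3.10.9).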

Results

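The study asked which transcripts of goat mammary epithelial cells respond to bacteria that cause mastitis, the inflammation of the udder. E. coli is a Gram-negative and S. aureus a Gram-positive cause of it. The deposited values cover 666 genes in 7 libraries, with 3 libraries of E. coli-infected cells, 3 of S. aureus-infected cells and 1 of uninfected cells. Library medians lay between 8.89 (S. aureus replicate 1) and 9.06 (S. aureus replicate 2), in the log-like units of the deposited table. The median range of a gene over the 7 libraries was 0.899 units and the largest was 3.59 units. Read depth is unknown, and the replicate spread is the only measure of precision.

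Over the 666 genes, a separation of the libraries by infection was not shown. The root-mean-square difference per gene averaged 0.506 units between libraries of the same infection and 0.491 units between libraries of different infections. The former average pools unlike groups. The SD of the per-gene difference was 0.269 to 0.469 units between E. coli libraries and 0.512 to 0.813 units between S. aureus libraries. Between libraries of different infections it ran from 0.306 to 0.732 units. Of the 10 ways to split the 6 infected libraries into 3 and 3, 5 separated the 2 sides at least as far as the real groups were separated (exact permutation p = 0.5, one-sided, smallest possible 0.1). The uninfected library was on average 0.438 units from the infected ones, while the infected libraries were on average 0.497 units from each other. By mean distance to the other 6 libraries the control ranked 4 of 7, and S. aureus replicate 1 stood farthest out at 0.66 units. Same-numbered E. coli and S. aureus libraries were closer on average (0.407 units over 3 pairs) than differently numbered ones (0.532 units over 6 pairs). This held for numbers 2 and 3 (0.354 and 0.306 units) but not for number 1 (0.561 units), as E. coli replicate 1 was closer to S. aureus replicate 3 (0.309 units). S. aureus replicate 1, far from all libraries, was still closest to its own number among the E. coli libraries. The SD of its per-gene difference was 0.553 units from E. coli replicate 1, 0.732 from replicate 2 and 0.632 from replicate 3. As same-numbered pairs were closer on average, the mean between infections was above that within them once these pairs were left out. In a test chosen after seeing the data, among the 4 splits that part all 3 numbered pairs, the real one separated the libraries farthest in this respect (0.0262 units, highest other 0.0106 units), an exact permutation p of 0.25 (one-sided), the smallest that 4 splits can give.

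**Figure D1:**
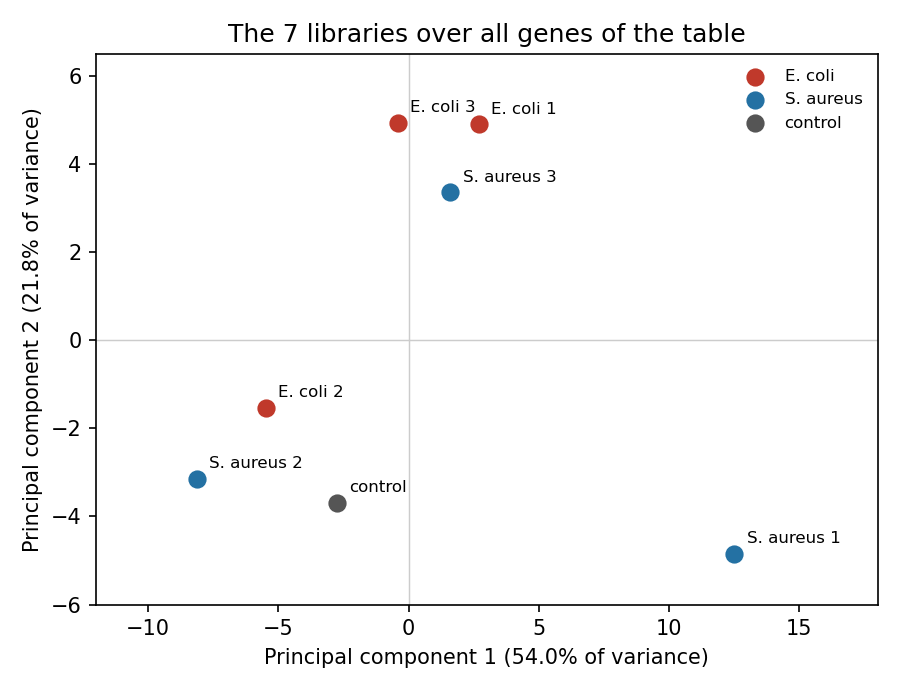
First and second principal components (54.0% and 21.8% of the variance) of the 7 libraries over 666 genes, in deposited log-like units; each point is 1 library, coloured by group. S. aureus replicates 1 and 2 lie at the ends of the first axis (12.5 and -8.13), and the control (-2.77) lies between infected libraries.

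The comparison of E. coli-infected with uninfected cells addresses the response to the Gram-negative bacterium. No gene changed past the threshold. The gene farthest above the control, ENSCHIG00000013589, had a value of 8.93 ± 0.14 (SD, n = 3) after E. coli and 7.68 in the control, a difference of 1.25 units (SE 0.43, limma adjusted p = 0.998). All 3 S. aureus libraries also lay above the control for this gene, at 8.36 ± 0.12 (SD, n = 3). The gene farthest below the control, ENSCHIG00000020380, had 7.29 ± 0.41 (SD, n = 3) after E. coli and 8.46 in the control, a difference of -1.17 units (SE 0.42, limma adjusted p = 0.998).

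With limma, 0 of 666 genes passed an adjusted p of 0.05 for E. coli against control, and 9 had an unadjusted p under 0.05 (2 higher, 7 lower), where 33.3 are expected by chance. Leaving out 1 infected library at a time moved this number between 2 (without E. coli replicate 3) and 26 (without S. aureus replicate 1), with 0 past the adjusted threshold each time. Differences exceeded 1 unit in 4 genes, and the interquartile range ran from -0.24 to 0.18 units. In 131 genes all 3 E. coli libraries were above the control and in 195 all were below it, together 48.9% of genes, where libraries drawn alike give 50%. The control had the highest mean over the 666 genes (9.32, other libraries 9.18 to 9.29). An excess of genes below it therefore cannot be told from an offset of that 1 library. The median half-width of a gene's unadjusted 95% interval was 0.851 units, and the adjusted threshold needs a larger difference. That width pools the spread of both infections, which was larger between S. aureus libraries. It may therefore be too wide for E. coli, and the low number of genes under the unadjusted threshold may partly follow from it. With library weights, chosen after seeing the data, 48 genes passed (14 higher, 34 lower), among them both genes named here. These calls depend on the weight of the control (2.28). The single control fixes its own group mean and leaves no residual, so the data do not measure that weight.

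The comparison of S. aureus-infected with uninfected cells addresses the response to the Gram-positive bacterium. No gene changed past the threshold here either. The gene farthest above the control, ENSCHIG00000005427, had 7.67 ± 0.33 (SD, n = 3) after S. aureus and 6.53 in the control, a difference of 1.14 units (SE 0.42, limma adjusted p = 0.998). ENSCHIG00000011606 followed with a difference of 1.07 units (SE 0.44), which was 0.26 units without S. aureus replicate 3. The gene farthest below the control was again ENSCHIG00000020380, at 7.49 ± 0.13 (SD, n = 3), a difference of -0.98 units (SE 0.42, limma adjusted p = 0.998).

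With limma, 0 of 666 genes passed for S. aureus against control, and 8 had an unadjusted p under 0.05 (4 higher, 4 lower). Differences exceeded 1 unit in 3 genes, and the interquartile range ran from -0.29 to 0.12 units. All 3 S. aureus libraries lay above the control in 58 genes and below it in 114, together 25.8% of genes against the 50% that libraries drawn alike give. The median difference over all genes was -0.09 units, so the excess below again cannot be told from an offset of the control library. The median half-width of a gene's unadjusted 95% interval was again 0.851 units. Leaving out 1 infected library at a time moved the number at an unadjusted p under 0.05 between 3 (without S. aureus replicate 3) and 40 (without S. aureus replicate 2), with 0 past the adjusted threshold each time.

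Both infections were also set side by side against the one control. With no gene called in either comparison, an overlap of calls could not be tested. The differences from the control had the same sign in 77.8% of genes, and correlated across genes at r = 0.66. Genes are not independent replicates, and the shared control alone produces such a relation. In 1000 simulations of unchanged groups against 1 control, r averaged 0.75 (95% of simulations between 0.71 and 0.79) and the share of equal signs averaged 76.9%. The observed covariance of 0.0677 was below the simulated mean of 0.142 (95% of simulations between 0.121 and 0.165). All 6 infected libraries lay above the control in 28 genes (4.2%) and below it in 78 genes (11.7%), where 14.3% in each direction are expected of libraries drawn alike and unpaired. The gap between the directions cannot be told from the higher mean of the control library over all genes. The simulations take all libraries as independent, leaving out the pairing by number. They assume that the control varies like an infected library and that both infections have the same spread. Whether the control is a pool of samples is not stated, and it cannot be split.

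The comparison of the 2 infections with each other has replicates on both sides. A single gene, ENSCHIG00000011606, passed the threshold in the main fit and lost the call under 8 of 15 alternatives. It was lower after E. coli, at 9.38 ± 0.41 (SD, n = 3), than after S. aureus, at 10.96 ± 1.44 (SD, n = 3). The difference was -1.58 units (SE 0.31, limma adjusted p = 0.00032). That SE comes from a spread shared by genes of like level; with the gene's own spread it was 0.867 units and the adjusted p 0.99 in the same limma model without moderation. The 3 S. aureus values were 9.84, 10.5 and 12.6, the control was 9.89, and the highest E. coli value was 9.81, so the groups did not overlap but S. aureus replicate 1 lay at the control level. Without S. aureus replicate 3 the difference was -0.77 units (limma adjusted p = 1). The limma adjusted p was 0.108 without E. coli replicate 1 and 0.286 without S. aureus replicate 2, and between 0.283 and 0.993 with median-centred values, quantile-normalised values or robust variances. With the replicate number as a block the adjusted p was 0.0569 and 0 genes passed. The next gene, ENSCHIG00000005427, was at 6.58 ± 0.86 (SD, n = 3) after E. coli and 7.67 ± 0.33 (SD, n = 3) after S. aureus, a difference of -1.09 units that did not pass (SE 0.30, limma adjusted p = 0.0861). Over 14 alternatives this difference ran from -1.35 to -0.60 units. The latter was without E. coli replicate 2 (limma adjusted p = 0.994), whose value was 5.59.

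Of the 666 genes, 1 passed with limma and 16 had an unadjusted p under 0.05 (6 higher and 10 lower after E. coli). The latter number was 5 without E. coli replicate 3 and 72 without S. aureus replicate 2. With the replicate block 62 had an unadjusted p under 0.05, 31 in each direction. By chance 33.3 are expected, so the count lay below that number without the block and above it with the block. Genes are not independent, so neither gap was tested. The 3 libraries of one infection did not overlap those of the other in 34 genes (22 higher and 12 lower after E. coli), 5.11% of genes. Chance gives 10% for 6 unpaired libraries and less for paired ones. The other 3 splits that part all 3 numbered pairs, a comparison chosen after seeing the data, gave 14, 35 and 20 such genes. Within the numbered pairs, the sign of the difference was the same in all 3 pairs for 174 genes (82 higher and 92 lower after E. coli), 26.1% against a chance share of 25%. The median half-width of a gene's unadjusted 95% interval was 0.601 units.

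**Figure D2:**
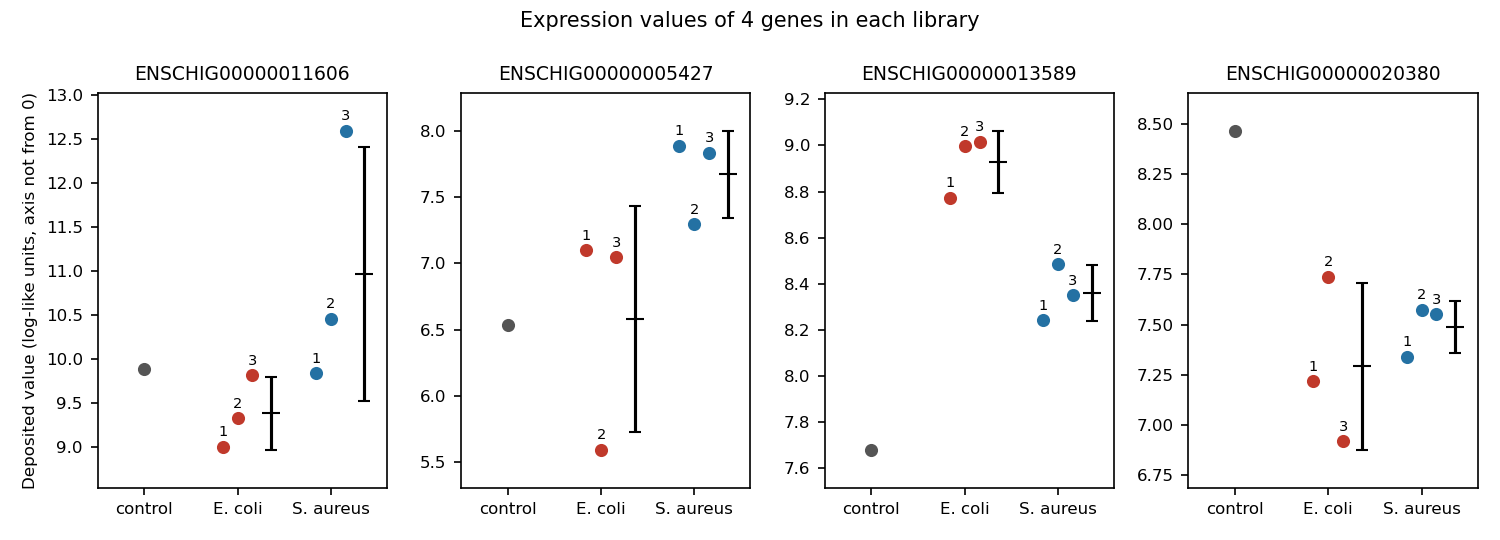
Deposited values (log-like units, axes not starting at 0) of 4 genes in the control, E. coli and S. aureus libraries; points are libraries numbered by replicate, and the bars show the mean ± SD of 3 libraries. S. aureus replicate 3 stands apart at 12.6 for ENSCHIG00000011606, and all 6 infected libraries lie above the control for ENSCHIG00000013589 and below it for ENSCHIG00000020380.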

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

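The comparison of the infections and the leaving out of each library were planned before the data were examined, and the tests on quantile-normalised values and on the expression level were set before their results were seen. The tests by splits, by pairings and by sides of the control were chosen after the results were seen.

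ENSCHIG00000011606 passed a test of the difference between the infections in the fit without the replicate block (-1.58 units, limma adjusted p = 0.00032) and not with it (adjusted p = 0.0569), with a difference from the control of -0.51 units after E. coli and 1.07 units after S. aureus. S. aureus replicate 3 is a candidate source of much of the difference, which was -0.77 units without it (adjusted p = 1); the call also ended without E. coli replicate 1 (-1.39 units, adjusted p = 0.108) or S. aureus replicate 2 (-1.84 units, adjusted p = 0.286). Of the 10 splits of the 6 infected libraries, 5 gave at least as many genes as the real one (1 gene, highest other 1); 10 splits are too few for a share under 0.05. Among the 4 splits that part all 3 numbered pairs, the real one gave 1 gene and the others 0, which is also too few splits. A response to S. aureus that varied between cultures stays open as a hypothesis, untested with 3 libraries, as does a technical fault in that library.

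In 7 genes every E. coli library lay on one side of the control and every S. aureus library on the other (5 above after E. coli and below after S. aureus, 2 the reverse). The difference was not tested for these genes as a set. They make 1.05% of the 666 genes, where libraries drawn alike and unpaired give 1.43%.

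The second pattern is that same-numbered E. coli and S. aureus libraries deviated together (r = 0.49, 0.59 and 0.31 across genes). Quantile normalisation changed the 3 correlations little (0.48, 0.57 and 0.3 after it). A constant shift of a library in deposited units neither makes nor removes such correlations. The test therefore does not decide whether another step of the authors' processing is a cause. Chance cannot be told apart from a shared origin of the numbers: 1 of the 6 possible pairings, the real one, reached the mean correlation of 0.46 (highest other 0.26), and 6 pairings are too few for a share under 0.05. A shared goat, culture day or sequencing batch behind each number may be the cause; the labels name none of these, so biological and technical origins stay open.

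The third pattern is a split of the genes along the axis on which S. aureus replicates 1 and 2 lie farthest apart, which carries 54.0% of the variance. Between these replicates of 1 group, 213 genes were higher in replicate 1 by over 0.5 units and 233 higher in replicate 2, and 32 (4.8%) differed by under 0.1 units, where a normal distribution of the same SD gives 9.74%. This pair was singled out as the farthest apart: over all 21 pairs of libraries, 13 had fewer genes within 0.1 units than the normal distribution gives and 8 had more. Quantile normalisation left the SD of the differences at 0.95 of its deposited 0.813 units. A constant shift of a library neither makes nor removes this SD, and quantile normalisation keeps the order of genes within a library. The test therefore does not decide whether another step of the authors' processing is a cause. For a bias that depends on the expression level, Spearman's rho across genes between the difference and the level was 0.18 (95% interval 0.11 to 0.25, Fisher's z). That rho lay under the bound set beforehand for arguing against such a bias, but the interval reached past it. The interval takes genes as independent and may be too narrow, so this bias stays open. A choice of the 666 rows on their variation also stays open, as it could not be tested on the chosen rows. A response to S. aureus that differed between cultures was not tested.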

How the results depend on the processing

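For S. aureus against control the count stayed at 0 under all 13 alternatives run, so that calls shared by both infections could not be tested. For E. coli against control it stayed at 0 under 12 of 13 and was 48 with library weights, an alternative chosen after seeing the data. Those weights ranged from 0.369 (S. aureus replicate 2) to 6.07 (E. coli replicate 3), and their estimation did not reach its tolerance. The control's weight of 2.28 is not measured by the data, as the control has no replicate. Between the infections the count of 1 became 0 with median-centred libraries, with quantile normalisation, with robust variances, with the replicate block and with unmoderated per-gene variances (the last also chosen after seeing the data), and ranged from 0 to 1 when each replicate was left out. It was 0 without E. coli replicate 1, S. aureus replicate 2 or S. aureus replicate 3. The 1 gene is ENSCHIG00000011606, whose difference stayed between -2.15 and -0.77 units over 15 alternatives with limma adjusted p from 0.000191 to 1. With unmoderated and robust variances the difference was the same -1.58 units with adjusted p of 0.99 and 0.993, so there the call ended through the spread assigned to the gene; with median-centred (-1.60 units, adjusted p = 0.313) and quantile-normalised values (-1.56 units, adjusted p = 0.283) the prior degrees of freedom became finite (30.3 and 31.2). The replicate block kept the difference at -1.58 units and gave an adjusted p of 0.0569. Of the 10 splits of the 6 infected libraries, 7 gave at least the real 16 genes at an unadjusted p under 0.05, the real split included. The highest count was 156, for E. coli replicate 1 with S. aureus replicates 1 and 3, which puts both replicates 1 on the same side. Such counts cannot be told from chance with 10 splits. The 4 splits that part all 3 numbered pairs gave 16 (real), 4, 18 and 4. No named difference changed sign. Alternatives planned for linear values (pseudocounts, expression filters, fold limits), for counts, for gene lists and for a separate table of long noncoding RNAs were not run, because the values, identifiers and files do not allow them. A filter on level was added in their place, dropping the 222 genes of lowest mean level, and changed no count of adjusted calls. The read depth and base are unknown, which limits what a unit means.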

Other observations

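The uninfected library was closest to the replicate 2 libraries of both infections. The SD of the per-gene difference from the control was 0.318 units for E. coli replicate 2 and 0.375 units for S. aureus replicate 2. For the other infected libraries it ranged from 0.415 (E. coli replicate 3) to 0.622 (S. aureus replicate 1). The closest pair of all 7 libraries was E. coli replicates 1 and 3 (0.269 units), and the farthest was S. aureus replicates 1 and 2 (0.813 units). No 2 libraries held identical values.

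For ENSCHIG00000020380 all 6 infected libraries lay below the control, and for ENSCHIG00000013589 all 6 lay above it. Both genes were picked as the farthest from the control after E. coli, which favours such a result. All 6 lay below the control in 11.7% of genes and above it in 4.2%. Libraries drawn alike and unpaired give 14.3% in each direction. The S. aureus libraries varied little around their mean in both named genes (SD 0.13 and 0.12 units, n = 3). Both differences rest on 1 control library, and neither passed the limma test in either comparison with it (adjusted p of 0.998 in each).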
